A study of Homo sapiens with 16 samples.

How the data were processed

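RNA from 5 prostate cancer cell lines (22Rv1, 42D, PC-3, V16A and LNCaP) was sequenced after depletion of ribosomal RNA, with and without RNase R, an exonuclease that degrades linear RNA from its 3' end and leaves closed circles. The 16 libraries formed 8 pairs. Each pair was one RNA preparation split into a portion with and a portion without RNase R, per the labels' protocols and treatment labels. Gene values, as deviations from the mean of their RNase R group, correlated at 0.704 to 0.880 within pairs. By this measure 7 of 8 libraries without RNase R matched their own partner best. The LNCaP library at 0 nM for 16 h (0.709 with its partner) matched the one at 0 nM for 4 h better. LNCaP gave 4 pairs, from cells starved of serum for 48 h and then kept for 4 or 16 h with 0 or 10 nM dihydrotestosterone (DHT), an androgen. The other lines gave 1 pair each, and the labels record no starvation or DHT for them. The protocol text names fewer lines than the sample labels do and speaks of duplicates, where the labels give 1 pair per line or condition, so the sample labels were followed.

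The deposited gene table held raw counts per Ensembl gene, and the deposited circRNA table held raw counts of back-splice reads per circRNA, judged from their whole-number values and their unequal column totals. Libraries were stranded and single-end, per the labels' protocols. The genome build was GRCh37 and the tools were STAR 2.5.3a, TopHat2 2.1.0, TopHat, bedtools and edgeR 3.12.1, per the submitters' processing notes, which do not say which tool made which table. Neither the circRNA caller nor the rule for reads that match several genes is recorded. A deposited name table paired circRNA names with a host gene, a circle type and exon numbers, and its start positions counted from 0, per the file headers and the lengths of 3002 single-exon circles. All circRNA positions are GRCh37 positions counted from 1. Of 60308 gene identifiers, 55739 received a symbol from GENCODE 29, which is built on GRCh38. GENCODE 29 was used for names, gene types, exon lengths and which genes overlap or share sequence, and for no position in the text. Identifiers left without a symbol may have one in a GRCh37 annotation. Gene lists were matched by symbol, so these identifiers are on no list. Of 84297 circRNAs, 43428 had an entry in the name table, and these held 91.7% of the circRNA counts.

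The 8 libraries without RNase R held 27988122 to 83665995 gene counts and 6966 to 13322 circRNA counts. The 8 libraries with RNase R held 11455042 to 27795470 gene counts and 61431 to 174992 circRNA counts. Confidence intervals and count floors (3 counts) cover counting error only, since the reads carry no molecular identifiers.

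Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The total share of circRNA counts was compared by an exact two-sided sign-flip permutation test over the 8 pairs. Single circRNAs and genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with a term for the pair, Benjamini-Hochberg adjustment and a threshold of 0.05. Gene counts were scaled by TMM after filterByExpr. circRNA counts were scaled by the library's total gene counts (as CPM, counts scaled to a total of 1e6), for circRNAs with at least 2 counts in at least 4 libraries. The same model with an interaction term compared the RNase R effect of the 4 LNCaP pairs with that of the pairs of the 4 other lines. DHT was tested in the 4 LNCaP libraries without RNase R for genes and in the 4 with RNase R for circRNAs (at least 2 counts in at least 2 libraries), with a term for hours, which leaves 1 residual degree of freedom. Cell lines other than LNCaP had 1 library per RNase R state, so their differences from the LNCaP mean were described as log2(CPM + 1) with no test. List medians of these lines were placed among 10000 random lists of the same size matched on expression in 20 bins.

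The 19 gene lists were androgen-induced genes, androgen-repressed genes, cholesterol and lipid synthesis, proliferation, luminal prostate, neuroendocrine, mesenchymal, epithelial and basal epithelial markers, markers of other cell types (fibroblast, endothelial and immune), ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, structured small noncoding RNAs, nuclear long noncoding RNAs, abundant housekeeping mRNAs, known circRNA host genes, regulators of circRNAs, and glucocorticoid and stress genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Named circRNAs were the 10 largest rises and up to 5 largest falls past the threshold that moved the same way in 8 of 8 pairs (a pair with no count in either library moved neither way) with a mean of at least 10 counts, and the circRNA with the most counts of each listed host gene. Named genes for RNase R and for DHT were the 10 largest rises and 10 largest falls past the threshold with at least 5 CPM that moved the same way in every pair or at both times. For the difference between lines and for circRNAs with DHT they were the 5 largest each way. For each cell line they were the 5 largest differences each way of genes with at least 10 CPM in the higher, outside the range of the LNCaP libraries and in the same direction with RNase R. The members of each list with the smallest p, or the largest differences, served as its examples, 4 at most. Other list members were named, after their values were seen, where 5 or fewer were called or moved against the rest. CSNK1G3 was always reported. Some genes that met these rules are not reported here.

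The models were tested on simulated counts with 200 genes changed by 2-, 4- or 8-fold in the real libraries. The changed genes or circRNAs were drawn from those at or above the median mean count. The simulated dispersion followed its fitted trend with count level, with no further spread between genes. Recovery may therefore be lower for real genes, above all for those with low counts. In the simulation of the RNase R comparison of genes, edgeR recovered 200 of 200 among 14472 genes, and in that of the DHT comparison it recovered 200 of 200 among 15261 genes. In the simulated RNase R comparison of 9420 circRNAs it recovered 0 of 67 at 2-fold, 20 of 67 at 4-fold and 38 of 66 at 8-fold. In the simulated DHT comparison of 10357 circRNAs it recovered 1 of 67, 22 of 67 and 36 of 66. In the simulated difference between lines it recovered 161 of 200 among 14472 genes and 0 of 200 among 9418 circRNAs, so that comparison of circRNAs had little power.

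The alternatives were other scalings (TMM from the circRNA counts, DESeq2 size factors, library totals), the Wald test of DESeq2 1.42.0, other count minimums, no replicate block (the pair term) or hours term, leaving out each pair or library in turn, and subsets of the lines. Scaling by nuclear protein-coding genes, TMM from those genes, a split of the libraries into the 22Rv1, 42D and PC-3 pairs against the V16A and LNCaP pairs, and a limit to circRNAs counted in every LNCaP library were added after the data had been seen. Shared sequence between genes was measured with words of 48 bases from GENCODE 29 transcripts. Figures were drawn with matplotlib 3.10.9. The 3 deposited tables of patient values, with 337 columns of single persons, were left out, as were the mean patient values of an annotation table, since none of these people is a sample of the series.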

Results

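Stranded RNA-seq of ribosomal RNA-depleted RNA was collected from 5 prostate cancer cell lines as 8 pairs of libraries, each pair 1 RNA with and without RNase R. LNCaP, an androgen-responsive line, contributed 4 pairs (0 or 10 nM DHT for 4 or 16 h after 48 h of serum starvation). The lines 22Rv1, 42D, PC-3 and V16A contributed 1 pair each. Libraries without RNase R held 27988122 to 83665995 gene counts (22Rv1 the most) and 6966 to 13322 circRNA counts. Libraries with RNase R held 11455042 to 27795470 gene counts and 61431 to 174992 circRNA counts. Mitochondrial ribosomal RNA took 58.7% ± 14.1 (SD, n = 8) of gene counts without RNase R and 4.31% ± 4.37 with it. In the libraries with RNase R, ENSG00000265150.1, which received no symbol, held 25.3% ± 6.25 of gene counts (SD, n = 8). AL355075.4, which overlaps the RNase P RNA gene RPPH1 on the same strand, held 22.9% ± 8.18. AL139099.4, which overlaps the signal recognition particle RNA gene RN7SL1, held 20.4% ± 3.38. Reads of such overlapping genes could not be told apart.

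The first comparison asked how far RNase R raised the share of circRNA counts. circRNA counts rose from 283 ± 109 to 6693 ± 2486 CPM of gene counts (SD, n = 8). The mean log2 change was 4.58 ± 0.60 (SD, n = 8 pairs), a 24.0-fold rise, and the share was higher in 8 of 8 pairs (exact two-sided sign-flip permutation p = 0.0078125, the smallest that 8 pairs can give). The change ranged from 13.9-fold in 42D to 57.4-fold in 22Rv1. The 22Rv1 value is uncertain, since fewer of its circRNAs without RNase R had a single count (19.8% against a median of 64.1%), and whether they passed another filter is not recorded. It was 4.60 ± 0.17 in the 4 LNCaP pairs and 4.57 ± 0.91 in the 4 pairs of the other lines, a difference of 0.04 on the log2 scale (exact permutation p = 0.9714 over 70 assignments). Scaled to gene counts without the mitochondrially encoded and structured small RNA lists, the rise was 9.19-fold and the difference -0.58 (2.91 ± 0.18 against 3.49 ± 0.45, SD, n = 4 each, exact permutation p = 0.05714). The structured list held 0.585% of gene counts without and 0.0945% with RNase R, and the mitochondrial list 61.4% and 5.97% (means, n = 8). This scaling thus took out mainly mitochondrial counts, and AL355075.4, AL139099.4 and ENSG00000265150.1 stayed in. Scaled to nuclear protein-coding counts, the rise was 34.8-fold and the difference -0.14 (5.05 ± 0.21 against 5.19 ± 0.27; exact permutation p = 0.4), so the sign of the difference depended on the scaling. The libraries of 22Rv1, 42D and PC-3 differed from the others in which genes had counts at all, so the change is also given within both sets. It was 4.57 in those 3 pairs and 4.59 in the 5 V16A and LNCaP pairs. The smallest exact p that these sets allow is 0.25 and 0.0625.

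**Figure D1:**
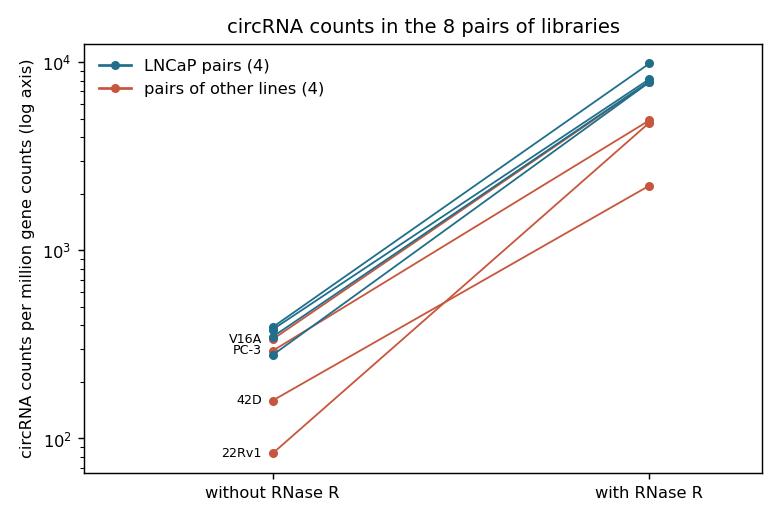
circRNA counts in CPM of gene counts (log axis) in each library without and with RNase R, with a line joining the 2 libraries of a pair (8 pairs, LNCaP and other lines in different colours). All 8 lines rise, from 83.3 to 390 without RNase R up to 2210 to 9857 with it.

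The second comparison asked which circRNAs resisted RNase R. Of 9420 circRNAs tested, 9259 rose and 7 fell (edgeR, adjusted p under 0.05), and 2680 were higher in 8 of 8 pairs, where a pair with no count in either library counts as neither higher nor lower. The count minimum can be met through the libraries with RNase R alone. Of those tested, 2236 had no count without RNase R, so their rise was fixed by the filter. With no filter except circRNAs with no count, edgeR called 11665 of 76231. The largest rise among those higher in 8 of 8 pairs was of a circle from BANP, which encodes a nuclear protein. circ_5978 of BANP (chromosome 16, 88061089 to 88071617, exons 8 to 11) had no count without and 3.64 ± 1.07 CPM with RNase R (SD, n = 8), at least 383-fold higher against a floor of 3 counts over the group (adjusted p = 2.0422e-38). circ_275 of RP11-146B14.1 (chromosome 9, 6880012 to 6893232, exons 6, 7 and 8) had 20 counts over the libraries without RNase R and 856 with it (6.95 ± 0.51, log2, SE). circ_113103 of PAPSS1, a sulfate donor synthesis gene, had 7 and 304 counts (6.76 ± 0.63). The other 7 named rises were of circles from COA1, CARHSP1, GNB1, PUM2, ZCCHC6, TMCC1 and MARK4, each with 1 to 3 counts over the libraries without RNase R. Only circ_90768 of ARHGAP5 (chromosome 14, 32559708 to 32586493, exons 2 and 3, 4030 bases) met the rule for a named fall, by 2.41 ± 0.58 (log2, SE; adjusted p = 5.1805e-05; lower in 8 of 8 pairs).

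The gene list of known circRNA hosts had a tested circRNA for 55 of its 60 genes. The circRNA with the most counts rose for 54 of them and fell for 1, ARHGAP5, and adjusted over the list alone 54 rose. Their median log2 change was 4.66. The circle with the most counts of HIPK3, a kinase gene (circ_30286, exon 2, chromosome 11, 33307959 to 33309057), rose from 1.43 ± 0.384 to 24.3 ± 10.5 CPM (SD, n = 8), by 3.98 ± 0.31 (log2, SE). That of ZKSCAN1, a zinc finger gene (circ_148331, exons 2 and 3, chromosome 7, 99621042 to 99621930), rose from 0.840 ± 0.485 to 25.2 ± 11.7 CPM, by 4.97 ± 0.33. That of CAMSAP1, a microtubule minus-end gene (circ_41913), rose by 5.30 ± 0.36, and that of SMARCA5, a chromatin remodeller gene (circ_79258), rose by 3.66 ± 0.34. The smallest rises on the list were of CDR1-AS (circ_178315), a circle with many miR-7 sites, by 2.19 ± 0.65, of MAN1A2 (circ_101465), a mannosidase gene, by 2.49 ± 0.30, and of ANKRD12 (circ_82144), an ankyrin repeat gene, by 2.60 ± 0.48. With TMM factors taken from the circRNA counts, MAN1A2 fell relative to other circRNAs (-0.72, adjusted p = 0.00277), while CDR1-AS (-0.79, adjusted p = 0.2575) and ANKRD12 (-0.60, adjusted p = 0.217) did not pass. Beside these circles, 12 of the 67 circRNAs checked by name lost their calls with these factors. For the kinase gene CSNK1G3, circ_150067 (host casein kinase 1 gamma 3; exons 2, 3 and 4, 536 bases, chromosome 5, 122881111 to 122893258), rose from 0.440 ± 0.235 to 7.24 ± 3.91 CPM (SD, n = 8), by 4.04 ± 0.40 (log2, SE; adjusted p = 7.0918e-22; 8 of 8 pairs). Its larger sibling circ_158496 (exons 2 to 6) rose by 3.47 ± 0.72. circ_94161 (exons 2 and 3) had no count without RNase R and 29 counts with it, at least 22.6-fold higher. Circles are named by their deposited identifiers.

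Circles of 6 or more exons rose less (median log2 4.08, 1701 of 1768 past the threshold) than those of 2 to 5 exons (4.45, 6815 of 6894), a description across circRNAs with no test of the difference. The 7 falls were not stable. They numbered 3 without the 42D pair, 3 without the PC-3 pair, 4 without the V16A pair and 3 without the LNCaP pair at 0 nM for 4 h. Scaled by TMM factors from the circRNA counts, which take out part of a shift that circRNAs share, the median log2 change was 1.83, and 2770 circRNAs rose and 40 fell.

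At the level of genes, mRNAs of replication-dependent histones, which end in a stem-loop and lack a poly(A) tail, rose (36 of 42), and ribosomal protein mRNAs (72 of 74), mitochondrially encoded RNAs (13 of 15) and abundant housekeeping mRNAs (20 of 27) fell, though none of these lists passed with an estimated correlation (adjusted p = 0.4529). Of 14472 genes, 5834 rose and 6072 fell relative to the typical gene (edgeR, adjusted p under 0.05). The largest named rises were of RNU4-2 (6.73 ± 0.41, log2, SE), the small nucleolar RNA SNORD46 (6.73 ± 0.32) and RNU4-1 (6.12 ± 0.47). Also among them were the histone genes HIST1H4C (6.35 ± 0.15), HIST1H4A (5.98 ± 0.14), HIST2H4B (5.72 ± 0.19) and HIST2H4A (5.71 ± 0.19). The overlapping gene AL355075.4 (6.11 ± 0.23) was another. So were ENSG00000124529.3 (6.50 ± 0.14) and ENSG00000265150.1 (5.77 ± 0.27), which received no symbol and are thus on no gene list. HIST1H4C went from 40.4 ± 41.6 to 3313 ± 3447 CPM (SD, n = 8; adjusted p = 3.5217e-13). The largest named falls were of the pseudogenes H3F3AP4 (-5.58 ± 0.30), H3F3AP6 (-5.50 ± 0.31), AC007182.2 (-5.47 ± 0.27) and RPS13P2 (-4.81 ± 0.28), of the splicing factor gene SF3B6 (-5.10 ± 0.25), the 7SK pseudogene RN7SKP80 (-5.03 ± 0.36), RPL36AL (-4.98 ± 0.26), the respiratory chain gene MT-ND3 (-4.91 ± 0.25), RWDD1 (-4.82 ± 0.23) and RAB9A (-4.80 ± 0.33), a Rab GTPase gene. All of these moved the same way in 8 of 8 pairs. Values of pseudogenes and of histone H4 copies are uncertain, since near-identical copies may have been counted together or apart.

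Among replication-dependent histones, 36 of 42 rose, 2 fell (HIST1H2AG and HIST1H1B) and 4 did neither, with a median of 4.47. HIST4H4 (5.43 ± 0.15) and HIST1H4E (5.38 ± 0.16) were among the clearest rises (camera adjusted p = 1.892e-25; adjusted p = 0.4529 with an estimated correlation). Of 74 ribosomal protein genes, 72 fell and 2 rose (RPS10 and RPL17), with a median of -2.26. RPS24 (-3.95 ± 0.17), RPL38 (-3.66 ± 0.16) and RPL21 (-3.48 ± 0.16) fell most clearly (adjusted p = 1.889e-16; adjusted p = 0.4529 with an estimated correlation). Of 15 mitochondrially encoded genes, 13 fell, 1 rose (MT-ND6, 0.97) and 1 did neither, with a median of -2.88 and with MT-CO2 at -4.19 ± 0.19 (adjusted p = 1.79e-06; adjusted p = 0.4529 with an estimated correlation). Of 27 abundant housekeeping genes, 20 fell, 1 rose and 6 did neither, with a median of -1.34. HSP90AA1, a chaperone gene, fell by 3.45 ± 0.16 (list adjusted p = 1.593e-05; adjusted p = 0.4529 with an estimated correlation). Of 53 known circRNA host genes, 40 rose, 7 fell and 6 did neither, with a median of 1.20. NFATC3 (3.51 ± 0.12), AMBRA1 (2.99 ± 0.13) and UBAP2 (2.26 ± 0.11) rose most clearly (adjusted p = 4.528e-06; adjusted p = 0.4529 with an estimated correlation). All 8 androgen-repressed genes tested fell, among them the glucuronosyltransferase genes UGT2B15 (-3.85 ± 0.25) and UGT2B17 (-3.26 ± 0.24) and BCHE (-3.16 ± 0.20), with adjusted p = 0.01004 for the list and adjusted p = 0.4529 with an estimated correlation. With library totals in place of TMM these 6 lists passed in the same directions.

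**Figure D2:**
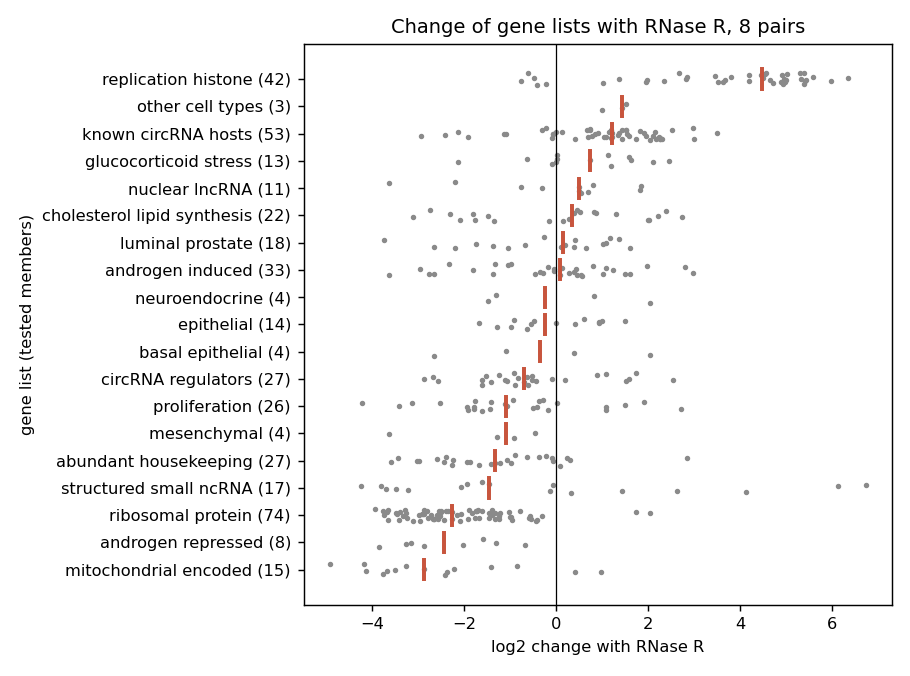
Change of each gene list with RNase R over 8 pairs (log2, edgeR), with 1 grey point per tested gene, a red bar at the list's median and the number of tested members in brackets. Replication-dependent histones lie at a median of 4.47 and mitochondrially encoded genes at -2.88.

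The other lists did not pass with camera and had members that went both ways or were few. Among proliferation genes 5 of 26 rose and 18 fell, among androgen-induced genes 14 of 33 rose and 13 fell, and among cholesterol and lipid synthesis genes 12 of 22 rose and 8 fell. Luminal prostate genes gave 7 rises and 8 falls of 18, epithelial genes 6 and 7 of 14, neuroendocrine genes 2 and 2 of 4, basal epithelial genes 2 and 2 of 4, mesenchymal genes 0 and 4 of 4, and markers of other cell types 3 and 0 of 3. Structured small noncoding RNAs gave 5 rises and 9 falls of 17, nuclear long noncoding RNAs 7 and 3 of 11, regulators of circRNAs 6 and 18 of 27, and glucocorticoid and stress genes 7 and 2 of 13. The structured list held 0.0945% of gene counts with RNase R (mean, n = 8). AL355075.4 and AL139099.4, which overlap its members RPPH1 and RN7SL1, are not on it and held 22.9% and 20.4%. Its tally therefore does not describe the reads of those loci. Of the 31 symbols of this list, 20 were found in the gene table. ENSG00000265150.1, with 25.3% of gene counts, received no symbol, so its share is not in that of the list. Whether it belongs on the list was not tested. PDGFRB, a marker of other cell types, lost its call without the PC-3 pair (0.77) or the LNCaP pair at 0 nM for 4 h (0.91), and LAMA3 of the basal list without the V16A pair (0.36) or the LNCaP pairs at 0 nM for 16 h (0.37), 10 nM for 16 h (0.31) or 0 nM for 4 h (0.35). In every list of this comparison the counts adjusted over the list alone were the same as those over all genes. Median, mean and camera direction differed in sign for the androgen-induced, lipid synthesis, luminal, neuroendocrine, epithelial and nuclear long noncoding RNA lists. Among single gene types, 62 of 86 small nucleolar RNA genes rose with a median of 2.53, and 17 of 20 microRNA genes rose with a median of 3.45. Protein-coding genes with 100 or more circRNA counts had a median of 0.27 (802 of 1692 rose), against -0.34 for those with 1 to 99 (1617 of 4672 rose) and 0.05 for those with none (2305 of 5415 rose). Only circRNAs with a recorded host gene were counted here, so genes with none may still host other circles. The CSNK1G3 gene rose by 0.74 ± 0.22 (adjusted p = 0.0057143; higher in 7 of 8 pairs). With library totals in place of TMM the median of all genes moved from -0.01 to -0.42 and 3571 genes rose.

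The next comparison asked whether RNase R acted differently in LNCaP pairs than in the pairs of the 4 other lines. AURKA, a mitotic kinase gene, changed by 0.78 ± 0.31 in LNCaP pairs and by -1.20 ± 0.16 in the others (SD, n = 4 pairs each), a difference of 1.97 ± 0.21 (log2, SE; edgeR adjusted p = 0.0047652). MCCC2 (leucine catabolism) differed by 2.39 ± 0.33, TRIP13 (meiotic and spindle checkpoint ATPase) by 2.12 ± 0.31, NCAM2 (a cell adhesion molecule) by 1.95 ± 0.39 and RNU2-64P by 2.93 ± 0.62. In the opposite direction, HIST3H2A differed by -3.31 ± 0.60, HIST1H3E by -2.89 ± 0.35, C5orf66 by -2.81 ± 0.34, HIST1H2AC by -2.27 ± 0.29 and EPB41L4A-AS1 by -2.20 ± 0.35. In all, 66 genes had the higher change in LNCaP pairs and 71 the lower, of 14472. Of the named genes, only AURKA and C5orf66 passed with each pair left out in turn. RNU2-64P was lost without 42D (2.77), PC-3 (3.32), V16A (2.41) or the LNCaP pairs at 0 nM 16 h (2.68), 10 nM 16 h (2.88) and 10 nM 4 h (2.62). NCAM2 was lost without 42D (adjusted p = 0.08067), PC-3 (1.92) or the LNCaP pairs at 0 nM 16 h (1.92), 10 nM 16 h (1.92), 0 nM 4 h (2.01) and 10 nM 4 h (1.98), and HIST3H2A without the same 6 pairs (-3.61, -3.44, -3.26, -3.30, -3.32 and -3.32). EPB41L4A-AS1 was lost without 42D (-2.19) or the LNCaP pairs in the same order (-2.38, -2.28, -1.92 and -2.18), and TRIP13 without LNCaP at 0 nM 16 h (2.06), 10 nM 16 h (2.03) and 0 nM 4 h (2.11). MCCC2 was lost without LNCaP at 0 nM 16 h (2.35), and HIST1H3E (-2.84) and HIST1H2AC (-2.23) without LNCaP at 10 nM 16 h.

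By list, 3 of 26 proliferation genes were higher in LNCaP pairs and 0 lower (6 and 0 adjusted over the list alone; median 0.45; CCNB1 1.21, BUB1 1.14), with camera adjusted p = 3.824e-11 and adjusted p = 0.3197 with an estimated correlation. Of 74 ribosomal protein genes, 2 were lower (RPL28 -1.76 and RPL37A -1.25) and 34 were lower adjusted over the list alone (median -0.57; adjusted p = 1.085e-17; adjusted p = 0.6447 with an estimated correlation). Of 15 mitochondrially encoded genes, 1 was lower (MT-CYB -1.18) and 8 adjusted over the list alone (median -0.83; adjusted p = 8.067e-07; adjusted p = 0.6447 with an estimated correlation). Of 42 replication-dependent histone genes, 3 were lower and 11 adjusted over the list alone (median -0.34; adjusted p = 8.067e-07; adjusted p = 0.7677 with an estimated correlation). Of 53 circRNA host genes, 2 were higher (KDM1A 1.21 and CORO1C 0.97) and also 2 adjusted over the list alone (median 0.22; adjusted p = 0.0005804; adjusted p = 0.7677 with an estimated correlation). Among the other 14 lists, EPCAM of the epithelial list (1.27) was the only single gene past the threshold over all genes, and no list passed. Adjusted over the list alone, EPCAM passed, as did 2 structured small noncoding RNAs that were lower, and regulators of circRNAs with 1 higher and 3 lower. In edgeR an unadjusted p under 0.05 was reached by 3 androgen-induced, 1 androgen-repressed, 2 lipid synthesis, 3 epithelial, 2 structured small, 1 nuclear long noncoding, 3 housekeeping, 10 circRNA regulator and 1 stress gene, and by 0 luminal, neuroendocrine, mesenchymal, basal and other cell type genes. Median, mean and camera direction differed in sign for the mesenchymal and structured small RNA lists. With library totals the median of all genes moved from -0.12 to 0.33, and the same 5 lists passed in the same directions. The single genes named in this paragraph depended on single pairs. CCNB1, BUB1, EPCAM, RPL28, RPL37A, MT-CYB, KDM1A and CORO1C lost their calls without 42D or the LNCaP pairs at 0 nM 16 h, 10 nM 16 h and 10 nM 4 h, and these genes except RPL28 without LNCaP at 0 nM 4 h. BUB1, EPCAM, RPL37A, MT-CYB and CORO1C lost them without PC-3, and CCNB1, BUB1 and CORO1C without V16A. Where lost, values ran from 1.12 to 1.33 for CCNB1, 0.96 to 1.28 for BUB1, 1.17 to 1.43 for EPCAM, -1.77 to -1.61 for RPL28, -1.36 to -1.10 for RPL37A, -1.24 to -1.10 for MT-CYB, 1.19 to 1.27 for KDM1A and 0.87 to 1.12 for CORO1C.

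For circRNAs, edgeR called 0 of 9420 as different between LNCaP and other pairs, with 129 at an unadjusted p under 0.05, and the Wald test of DESeq2 also called 0 (86 at an unadjusted p under 0.05). Without the 42D pair edgeR called 1. The smallest p was that of circ_141366 of SLMAP (difference 8.47 ± 1.88, log2, SE; adjusted p = 0.064463), which was chosen after its value was seen. Gene calls in this comparison depended on single pairs. They were 239 higher and 596 lower without the 22Rv1 pair, 9 and 7 without 42D, 47 and 28 without PC-3, 40 and 40 without V16A, and 3 and 5, 2 and 1, 13 and 12, and 10 and 4 without each LNCaP pair in turn (0 nM 16 h, 10 nM 16 h, 0 nM 4 h and 10 nM 4 h). With library totals or with no replicate block (no pair term) edgeR called 0 genes (500 and 589 at an unadjusted p under 0.05), and the Wald test of DESeq2 called 251 higher and 220 lower. A term for the RNase R effect of the 22Rv1, 42D and PC-3 pairs leaves V16A as the only pair to set against LNCaP, so that fit cannot decide.

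The DHT comparison asked which genes answered androgen in LNCaP cells at both 4 and 16 h. Classic androgen targets rose. KLK3, which encodes prostate-specific antigen, went from 9.92 ± 3.02 to 101 ± 38.7 CPM (SD, n = 2 each), by 3.30 ± 0.21 (log2, SE; adjusted p = 1.4771e-13). KLK2, a related kallikrein gene, rose by 4.15 ± 0.19, and TMPRSS2, a transmembrane serine protease gene, from 12.4 ± 1.53 to 110 ± 36.2 CPM. Of 15261 genes, 273 rose and 164 fell (edgeR, adjusted p under 0.05), and with library totals in place of TMM 150 rose and 235 fell. Other large rises were of CHRNA2 (4.52 ± 0.24), a nicotinic receptor subunit gene, TRGC1 (3.87 ± 0.33), a T cell receptor gamma constant segment, MAF (3.48 ± 0.23), a transcription factor gene, TRPM8 (3.24 ± 0.29), a cold-sensing channel gene, ST6GALNAC1 (3.14 ± 0.25), a sialyltransferase gene, and KLK4 (2.65 ± 0.16). The largest falls were of AKR1C2 (-1.61 ± 0.22), whose enzyme inactivates DHT, RAP2B (-1.56 ± 0.15), a Ras-like GTPase gene, AC092894.1 (-1.45 ± 0.22), HMOX1 (-1.41 ± 0.21), the heme oxygenase gene, TMEM38B (-1.30 ± 0.18), SYTL2 (-1.24 ± 0.22), ABCA1 (-1.22 ± 0.18), a cholesterol exporter gene, MAN1A1 (-1.18 ± 0.16), ME1 (-1.13 ± 0.17), the malic enzyme gene, and ANKRD16 (-1.12 ± 0.20). CSNK1G3 differed by 0.07 ± 0.14 (adjusted p = 0.97929), with the opposite sign (-0.09) under library totals. With no hours term 17 of the 42 named genes lost their calls in the fit on all 4 libraries. Fits on 3 libraries also had no hours term, so calls lost in them cannot be put down to the library left out alone. They numbered 20 (0 nM at 16 h left out), 22 (10 nM at 16 h), 24 (0 nM at 4 h) and 10 (10 nM at 4 h). Among the genes of this paragraph, those lost with 0 nM at 16 h left out were TMEM38B (-1.26), SYTL2 (-1.06) and ANKRD16 (-1.01), with 10 nM at 16 h AC092894.1 (-1.04), TMEM38B (-0.75), SYTL2 (-0.99), ABCA1 (-0.98) and MAN1A1 (-0.87), and with 10 nM at 4 h ANKRD16 (-0.75). With 0 nM at 4 h left out they were TRGC1 (4.33), AC092894.1 (-1.38), TMEM38B (-1.17), SYTL2 (-1.41), ABCA1 (-1.29), MAN1A1 (-1.23), ME1 (adjusted p = 0.09421) and ANKRD16 (-1.14).

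**Figure D3:**
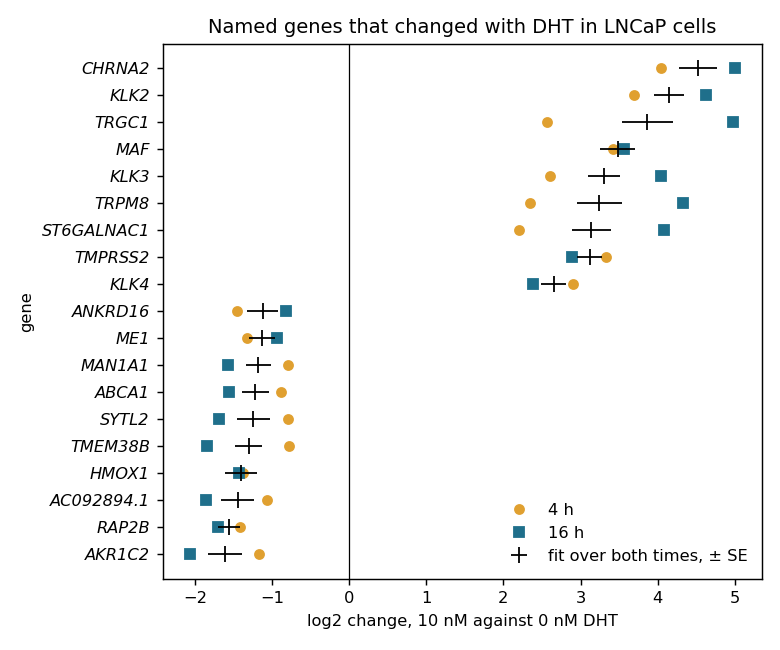
log2 change with 10 nM DHT of named genes in LNCaP cells without RNase R, at 4 h (circles) and 16 h (squares, 1 library per condition and time) and fitted over both times (crosses, ± SE). Every gene drawn lies on the same side of 0 at both times.

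Of 32 androgen-induced genes, 29 rose, 1 fell (TSC22D3, a glucocorticoid-induced leucine zipper gene, -0.57) and 2 did neither (EAF2 and CDC14B). KLK2, TMPRSS2 and KLK4 were among the clearest rises, and the list's median was 1.58 (camera adjusted p = 1.11e-196; adjusted p = 0.3286 with an estimated correlation). Of 9 androgen-repressed genes, 0 rose and 4 fell (OPRK1 -1.10, UGT2B15 -0.78, ACKR3 -0.70 and UGT2B17 -0.68), and adjusted over the list alone 1 rose and 5 fell (adjusted p = 1.417e-05; adjusted p = 0.7689 with an estimated correlation). Of 18 luminal prostate genes, 6 rose, and these are also androgen-induced genes (adjusted p = 6.283e-43; adjusted p = 0.5358 with an estimated correlation). Among 22 cholesterol and lipid synthesis genes 3 rose, among them ELOVL5 (0.97), and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.003266). Among 26 proliferation genes 2 rose, the replication helicase genes MCM4 (0.73) and MCM2 (0.85), and 3 adjusted over the list alone (adjusted p = 0.0002694). Among 14 glucocorticoid and stress genes 4 fell (ASNS -0.75, CHAC1 -0.81, DDIT4 -0.56 and NR3C1 -1.52), and adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.002354). Among 5 mesenchymal genes only SNAI2 rose (3.42 ± 0.34; adjusted p = 0.003084 for the list). Of 38 histone genes only HIST1H2AJ rose (0.71; adjusted p = 1.417e-05 for the list, median 0.27), and in fits on 3 libraries with no hours term it stood at -0.01 without the 10 nM library at 4 h and lost its call without 0 nM at 16 h (0.24), 10 nM at 16 h (1.18) or 0 nM at 4 h (1.39). The 15 mitochondrially encoded genes had a median of 0.26 with 0 called in edgeR (4 at an unadjusted p under 0.05; adjusted p = 0.0001501 for the list). With an estimated correlation the adjusted p was 0.7821 for the lipid synthesis, proliferation, stress, mesenchymal, histone and mitochondrial lists. This fit leaves 1 residual degree of freedom, from which a correlation can hardly be estimated (it came out as 1 for the mitochondrial list). The adjusted p values with an estimated correlation therefore cannot decide for any list of the DHT comparison. With library totals the median of all genes moved from 0.003 to -0.16, and these 9 lists passed in the same directions. In fits on 3 libraries with no hours term, further calls were lost. Without the 0 nM library at 16 h, UGT2B15 (-0.74), ACKR3 (-0.57), UGT2B17 (-0.70), ELOVL5 (0.93), MCM4 (0.26), MCM2 (0.37), ASNS (-0.76), CHAC1 (-0.48), DDIT4 (-0.53) and NR3C1 (-1.54) lost their calls. Without 10 nM at 16 h, OPRK1 (-1.07), UGT2B15 (-0.59), ACKR3 (-0.70), UGT2B17 (-0.32), ELOVL5 (0.68), MCM4 (0.61), MCM2 (0.73), ASNS (-0.67), CHAC1 (-1.16), DDIT4 (-0.59) and NR3C1 (-1.14) did. Without 0 nM at 4 h, OPRK1 (-0.93), UGT2B15 (-0.80), ACKR3 (-0.83), UGT2B17 (-0.58), ELOVL5 (1.08), MCM2 (1.38), SNAI2 (3.10), ASNS (-0.75), CHAC1 (-1.06), DDIT4 (-0.59) and NR3C1 (adjusted p = 0.5642) did. Without 10 nM at 4 h, ACKR3 (-0.71), MCM4 (0.71), MCM2 (0.84), CHAC1 (-0.52), DDIT4 (-0.52) and NR3C1 (-1.97) did.

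The remaining lists did not pass. Of 14 epithelial genes 1 rose (GRHL2 0.84) and 1 fell (OCLN -0.59), of 27 housekeeping genes FTH1 fell (-0.66), and of 53 circRNA host genes MBOAT2 rose (1.17) and TMEM56 fell (-0.91). edgeR called 0 of 3 neuroendocrine, 0 of 4 basal epithelial, 0 of 2 other cell type, 0 of 74 ribosomal protein, 0 of 16 structured small noncoding RNA, 0 of 12 nuclear long noncoding RNA and 0 of 27 circRNA regulator genes (0, 1, 1, 0, 3, 2 and 1 at an unadjusted p under 0.05). The epithelial list had a median of -0.01, a mean of 0.04 and camera direction up. In fits on 3 libraries with no hours term, GRHL2 (0.91), OCLN (-0.68), FTH1 (-0.26) and TMEM56 (-1.13) lost their calls without 0 nM at 16 h, as did OCLN (-0.37), FTH1 (-0.56) and TMEM56 (-0.37) without 10 nM at 16 h, GRHL2 (0.90), OCLN (-0.48) and TMEM56 (-0.56) without 0 nM at 4 h, and GRHL2 (0.35) and FTH1 (-0.86) without 10 nM at 4 h. Adjusted over the list alone, VWF (1.65) of the other cell type markers passed as well. The LNCaP libraries were 2 against 2, and the Wald test of DESeq2 called 115 rises and 47 falls. Without 1 library and with no hours term, rises and falls were 57 and 12 (0 nM at 4 h left out), 87 and 32 (0 nM at 16 h), 132 and 19 (10 nM at 16 h) and 180 and 120 (10 nM at 4 h), and with no hours term alone 106 and 32.

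The same comparison for circRNAs, in LNCaP libraries with RNase R, found circles that were counted in both libraries of 1 DHT arm and absent from the other. Of 10525 circRNAs, 2 rose and 4 fell (edgeR, adjusted p under 0.05; 261 at an unadjusted p under 0.05). circ_30029 of STK39, a stress kinase gene (exons 9 to 14, chromosome 2, 168920010 to 168986268), had 72 and 103 counts with DHT and none without it, at least 63.5-fold higher (adjusted p = 4.1882e-35; floor of 3 counts over the group). circ_72888 of ACAP2 had 27 and 30 counts with DHT and none without it, at least 20.7-fold higher. circ_42407 of CCAR1, a cell cycle and apoptosis regulator gene (exons 4 to 6, chromosome 10, 70497602 to 70502326), had 47 and 33 counts without DHT and none with it, at least 24.5-fold lower. circ_3278 of CIRBP, a cold-inducible RNA-binding protein gene, circ_108381 of HERC1 and circ_24364 of RIMS1 were at least 14.7-, 11.3- and 10.4-fold lower. circ_150067 of CSNK1G3 went from 11.2 ± 1.02 to 9.89 ± 1.81 CPM (SD, n = 2 each; -0.19 ± 0.22, log2, SE; adjusted p = 0.99925). Among the 5660 circRNAs with a count in each of the 4 libraries, a limit that leaves out all 6 called circles by construction, edgeR called 0 (219 at an unadjusted p under 0.05). The Wald test of DESeq2 and edgeR with no hours term also called 0 (31 and 672 at an unadjusted p under 0.05). With 1 library left out and no hours term, 0 rose and 0 fell (0 nM at 16 h or at 4 h left out, 339 and 311 at an unadjusted p under 0.05 in edgeR, with STK39 and ACAP2 at adjusted p = 0.8325 and 0.7326), 0 rose and 15 fell (10 nM at 16 h) or 1 rose and 11 fell (10 nM at 4 h). With a library left out, circles counted in that arm alone fail the count minimum. The 4 falling circles were therefore not tested without either 0 nM library, nor STK39 and ACAP2 without either 10 nM library, where the 4 falling circles kept their calls. A grouping of the same libraries by hours left 8 circRNAs with 20 or more counts in 1 group and none in the other, and a crossed grouping left 15, against 10 for the grouping by DHT.

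Between cell lines, PC-3 stood farthest from LNCaP. Its mesenchymal genes lay above LNCaP by a median of 4.16 on the log2 scale (16 of 17 higher, above 100% of random lists). These included CD44, an adhesion receptor gene (483 CPM against 0.0170), CAV1, the caveolin 1 gene (77.4 CPM against no count), and AXL, a receptor kinase gene (58.0 CPM against no count). Basal epithelial genes such as LAMB3 (72.8 against 0.211 CPM) had a median of 3.73 (6 of 6 higher). Epithelial genes had a median of -1.65 (14 of 14 lower), with CDH1, the E-cadherin gene, at 8.52 against 241 CPM and RAB25 at 0.0195 against 38.9 CPM. Luminal prostate genes had a median of -2.82, with FOLH1, which encodes prostate-specific membrane antigen, at 0.176 against 413 ± 48.6 CPM (SD, n = 4 LNCaP libraries). Other PC-3 genes far above LNCaP were ANXA2 (636 CPM), PLAU, the urokinase gene (520 CPM), and IL1B, an interleukin gene (536 CPM). UGT2B15, SYT4, PRUNE2 and SPON2 were far below it. A count of 0 allows up to 0.0586 CPM in PC-3 and up to 0.0283 CPM in the mean of LNCaP.

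In 22Rv1, PEG10, a retrotransposon-derived gene of the neuroendocrine list, stood at 344 CPM against 0.226 ± 0.0789. HGF, the hepatocyte growth factor gene (263 CPM), GUCY1A2 (385), MUC13 (149) and HSPB6 (171) were also far above LNCaP, whereas SPON2, TFPI, ADAMTS1, MME and ACKR3 were far below. Luminal prostate genes lay below LNCaP (median -1.54, 16 of 18 lower; SLC45A3 2.15 against 94.1 CPM) and ribosomal protein genes too (median -1.20, 71 of 75 lower, but -0.39 with 57 lower in the libraries with RNase R). In 42D, androgen-induced genes had a median of 1.35 (27 of 34 higher; FKBP5 278 against 46.1 CPM, MAF 57.0 against 8.39). ADGRG6, an adhesion GPCR gene (0.159 against 611 CPM), TFPI, BCHE, GULP1 and SPON2 were far below. Among the genes farthest above LNCaP in 42D were RPL9P9 (77.2 CPM) and 3 identifiers that received no symbol, of which ENSG00000266037.1 also led in PC-3. RPL9P9 shares sequence with other genes and has no count in LNCaP, so its value is uncertain. V16A had the fewest genes at least 2-fold away from LNCaP and outside its range, 678 higher and 489 lower among 6786 genes at 10 CPM or more, against 2087 and 1270 of 7658 in PC-3, 1523 and 1142 of 7105 in 22Rv1, and 1018 and 762 of 6960 in 42D. KLK3 reached 974 CPM in V16A against 65.1 ± 67.0. FUCA2 (29.7 CPM), PEG10 (34.7), HIST1H2AG (238) and HIST1H2AH (82.8) were higher, and ETV1, an ETS factor gene (0.0411 against 80.6 CPM), KCNJ3, ADGRG6, TLL1 and KCNH8 were lower. CSNK1G3 ranged from 25.7 CPM in PC-3 to 43.7 in 22Rv1 against 33.2 ± 0.919 in LNCaP.

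Proliferation genes were higher than in the serum-starved LNCaP cells in all 4 lines (26 of 26 in each, medians 2.31 in 42D, 3.01 in PC-3 and 2.39 in V16A, above 100% of random lists). Replication-dependent histone genes were higher too (medians 0.94 in 22Rv1, 2.42 in 42D, 2.88 in PC-3 and 2.54 in V16A), and androgen-repressed genes lower (medians -2.08, -1.40, -4.72 and -2.58 in the same order, below all random lists, with 4, 2, 3 and 0 of 10 members higher, among them MET at 6.15 in PC-3). Androgen-induced genes had medians of -0.56 in 22Rv1, -1.80 in PC-3 and 0.44 in V16A, beside a standard deviation of 0.85 between the LNCaP libraries, which differ in DHT. Lipid synthesis genes were lower in PC-3 (median -1.05). The 5 neuroendocrine genes had medians of 1.43 in 22Rv1 (4 higher), 2.04 in PC-3 (3 higher, 2 lower) and 0.67 in 42D (5 higher). In the libraries with RNase R those of 22Rv1 and PC-3 were 0.73, inside the middle 95% of random lists (percentiles 92.76 and 91.25). Mitochondrially encoded genes were lower in 42D (-1.13) and V16A (-0.80) and higher in 22Rv1 (0.67). Regulators of circRNAs had medians of 0.57 in 22Rv1, 0.46 in PC-3, 0.19 in 42D and 0.18 in V16A. Glucocorticoid and stress genes had a median of -0.70 in PC-3, at percentile 3.04 of random lists, just inside the middle 95%, and outside it with 0.1 CPM in place of 1 CPM added (percentile 0.2) or with library totals (percentile 0.54). Markers of other cell types had one of -0.26, inside it. Nuclear long noncoding RNAs had a median of -1.39 in PC-3 (-2.30 with 0.1 CPM added). Housekeeping genes had one of 1.09 in PC-3 and 0.47 in V16A, and markers of other cell types one of 0.50 in V16A on 3 members. Epithelial genes had one of -0.82 in 22Rv1, and of -0.44 at percentile 5.06, inside the middle 95%, in the libraries with RNase R. Structured small noncoding RNAs lay at -1.72 in 22Rv1. Known circRNA host genes had a median of -0.34 and epithelial genes one of -0.49 in 42D. Each line had 1 library and a different culture from LNCaP, so these differences have no replicate check.

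**Figure D4:**
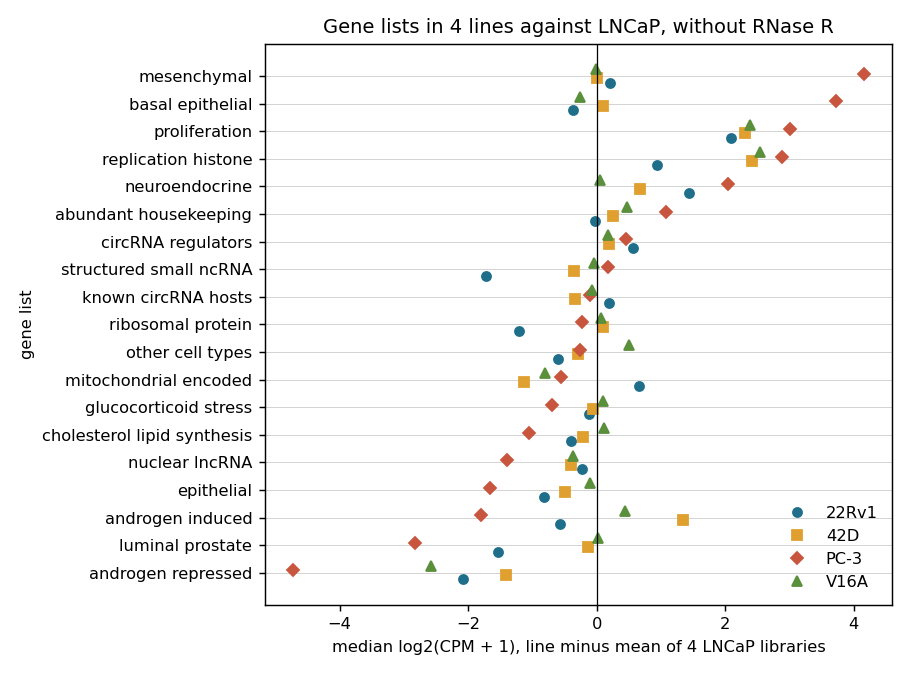
Median over the members of each gene list of log2(CPM + 1) in a line's library without RNase R minus the mean of the 4 LNCaP libraries (1 library per line, 1 symbol per line). Proliferation reaches 3.01 and mesenchymal genes reach 4.16 in PC-3.

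The last comparison asked whether circRNA differences between lines went with those of their host genes. Across 1998 genes, the difference of a line from LNCaP in the circRNA with the most counts and that in its host gene had a Spearman correlation of 0.593 in PC-3, 0.473 in V16A, 0.386 in 42D and 0.372 in 22Rv1. These 4 correlations are across genes, which are not independent replicates, and carry no p-value. For genes with a mean of at least 20 circRNA counts the correlations ran from 0.472 to 0.668, over 619 genes. With circRNA counts from the libraries without RNase R they ran from 0.148 to 0.401.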

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

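The tests of histone mRNA ends, of counts lost from single LNCaP libraries, of counts moved between circles and of ribosomal protein transcription were chosen after the result was seen, and so were the later length matchings of the histone test and the test of shared sequence over genes counted in all 3 libraries, with its limits. Of 42 groups of up to 8 libraries or pairs examined for a value far from the others, 10 had one (pairs with no count in 1 of their libraries left out). Chance gives about 1 in 20 for independent draws from 1 population. These groups mix LNCaP with other lines and share libraries, so that rate does not apply to them.

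The 22Rv1 libraries stood apart in several measures. The 22Rv1 library without RNase R had the most gene counts, 83.67 against a median of 35.21 (in units of 1e6). In it 19.8% of detected circRNAs had a single count (95% Wilson interval 17.93% to 21.82%), against a median of 64.1%. With RNase R this share was 25.9% (25.2% to 26.61%), against 47.3%, and mitochondrial ribosomal RNA held 14.37% of gene counts (14.354% to 14.383%), against 2.83%. The change with RNase R in the 22Rv1 pair, compared with the median of 8 pairs, was 2.98 against 7.01 for RNU4-2, 2.01 against 6.37 for RNU4-1, 6.91 against 5.79 for ENSG00000265150.1, and -1.21 against 0.95 for the CSNK1G3 gene (log2). In the LNCaP pair at 0 nM for 16 h, SF3B6 changed by -3.27 against a median of -5.24 and RN7SKP80 by -2.47 against -5.09.

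The RNase R effect differed between the LNCaP pairs and the other pairs, by the interaction test of edgeR, for RNU2-64P (2.93), MCCC2 (2.39), TRIP13 (2.12), AURKA (1.97), NCAM2 (1.95), HIST3H2A (-3.31), HIST1H3E (-2.89), C5orf66 (-2.81), HIST1H2AC (-2.27) and EPB41L4A-AS1 (-2.20). Adjusted p ran from 0.00477 for AURKA to 0.0451 for RNU2-64P. With library totals in place of TMM, or with no replicate block, edgeR called 0 genes, so all these calls were lost.

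The real split gave more calls than every other one for the RNase R effect on circRNAs (9266 calls, highest of the other splits 0; 1 of 30 splits) and on genes (11906 calls, highest other 0; 1 of 30 splits). The other splits exchanged the libraries within some of the pairs. An exchange carries the RNase R effect into the residual spread and lowers the calls, so this rank alone cannot exclude chance. For the difference of genes between LNCaP and other pairs (137 calls, highest other 0, 1 of 35 splits) the test cannot decide. Every other split mixes LNCaP pairs with other lines, which adds to the residual spread and lowers the calls. The real split follows cell line, culture, sequencing depth and nearly the set of libraries with zero counts described below. For circRNAs in that comparison the test is void, since with 0 calls all 35 of 35 splits give as many whatever the data (highest other 1).

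The first pattern was the rise of replication-dependent histone mRNAs with RNase R (median log2 4.47, lower quartile 2.71). The 133 protein-coding genes with exon lengths between the quartiles of the list (median 988 against 495.5 bases) had a median of -1.599 (20 rose, 96 fell). Earlier matchings on length and expression used longer genes (median 2168 and 3010 bases, the latter for 28 of 42 histone genes) and gave -1.56 and -0.51. These values argue against short transcripts as the cause at those lengths. All these sets were longer than the histone genes, so they cannot decide for transcripts as short as those. A candidate explanation is the lack of a poly(A) tail, since 9 polyadenylated histone genes had a median of -0.5775, with H3F3A at -3.08 and H3F3B at -3.02, although H2AFY (0.41), H1F0 (1.12) and H1FX (1.64) rose. These 9 genes were longer too (median 2344 against 495.5 bases), so the contrast cannot separate the tail from length. The stem-loop end itself was not tested, so the lack of a tail stays a hypothesis. No biological explanation was tested, because the design gives no group in which histone mRNA ends differ.

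The second pattern was the set of circRNAs counted in 1 DHT arm and absent from the other. A change of the host gene is argued against, since 1 of the 6 called circles had a host that passed in the same direction (STK39, 1.07, adjusted p = 1.191e-05 in edgeR), and so is a move of counts to other circles of the host, which made up the missing counts for 0 of 6. In the arm with no counts minus the other arm, the host's other circles stood at -4.11 CPM for STK39 and -9.93 for RIMS1. They stood at -0.93 for HERC1, -0.89 for CCAR1, 0.43 for ACAP2 and 0.07 for CIRBP. A negative value is a move in the same direction as the called circle, and these values carry no test. Loss of circles from single libraries whatever the treatment may account for the pattern: circRNAs absent from 1 arm with 20 or more counts in the other numbered 10 for the DHT split, 8 for the hours split and 15 for the crossed split. In the same libraries 38 of 7003 values were 0 where at least 10 counts were forecast, against 0.0272 by counting error, in 29 circRNAs. A response to DHT stays open for single circles and would need further replicates.

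The third pattern was a set of genes, RPL9P9 among them, that had counts in the 22Rv1, 42D and PC-3 libraries and none in all V16A and LNCaP libraries (RPL9P9 without RNase R: 564, 6310 and 1890 counts against 0 in 5 libraries). Reads matching several places and counted in some libraries only are a candidate explanation. Such genes, those that raised the question left out, were 5 of 3887 with 50% or more shared sequence against 3 of 31317 with none. That is 13.43 times the share, though few, with ratios of 9.22 at 95% (1 gene) and 4.75 with any sharing. Over genes counted in all 3 libraries alone, the ratios were 19.15 at 50%, 26.16 at 95% and 2.49 with any sharing (Fisher exact p = 0.2456 for the last). An earlier ratio of 0.1816 decides nothing, as 382 of its 457 genes without shared sequence were counted in 1 library. Reads added to every gene they match would leave gene pairs with equal counts, and 0 such pairs were found against a mean of 5.7 (range 0 to 14) in 10 sets of V16A and LNCaP libraries, once the pair RPL9P9 and ENSG00000230903.5 that raised the question was left out. Lower transcription of ribosomal protein genes in V16A and LNCaP, the biological explanation, is argued against by a median difference of 0.3846 over 75 ribosomal protein genes, where a value below -1 was needed. Different handling of such reads stays a hypothesis, and whether the libraries were counted in separate batches cannot be read from the labels.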

How the results depend on the processing

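Scaling by nuclear protein-coding genes, TMM from those genes, the split into 22Rv1, 42D and PC-3 pairs against V16A and LNCaP pairs, and the limit to circRNAs counted in all 4 libraries were chosen after the data had been seen. The direction of the total circRNA share held under every alternative run, with mean log2 changes from 3.20 to 5.12, and was 4.57 and 4.59 within the 2 sets of pairs, where 3 and 5 pairs cannot pass the threshold. The difference between LNCaP and other pairs in that change was 0.04 as planned, -0.58 without the mitochondrially encoded and structured small RNA lists and -0.14 with nuclear protein-coding scaling. For gene changes with RNase R, 1601 values of named genes kept their side of the threshold, 38 lost it and 2 reversed, and for named circRNAs these numbers were 1207, 50 and 6. For DHT they were 324, 131 and 2 (genes) and 36, 18 and 0 (circRNAs), and for the gene difference between lines 122, 130 and 0. Of the values of cell lines against LNCaP, 55 stayed within a standard deviation of the LNCaP libraries, 172 moved farther and 2 reversed. Where no cause is given below, the cause was not tested.

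Rises and falls of circRNAs with RNase R (9259 and 7) became 2770 and 40 with TMM factors from the circRNA counts and 1540 and 24 with the Wald test of DESeq2 on size factors from the circRNA counts, both of which take out part of a shift shared by circRNAs by construction (median log2 1.83 and 1.06). Under these MAN1A2 stood at -0.72 and -0.62, ANKRD12 at -0.60 and -0.49, and CDR1-AS at -0.79 and -0.60. Falls were 4 with DESeq2 size factors from the gene table, 2 with no filter, 3 with at least 5 counts (3869 rises among fewer circRNAs), 3 with nuclear protein-coding scaling, 3 in the 4 LNCaP pairs, 4 in the V16A and LNCaP pairs and 3 to 7 with single pairs left out (7579 to 8576 rises). The pairs of the 4 other lines gave 5774 and 0, and those of 22Rv1, 42D and PC-3 gave 1593 and 0, with fewer samples. Genes that rose with RNase R numbered 3571 with library totals, where LAMA3 stood at -0.0013; it stood at -0.11 in the 22Rv1, 42D and PC-3 pairs.

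The gene difference between lines (66 and 71) became 0 and 0 with library totals and with no replicate block. A term for the 22Rv1, 42D and PC-3 pairs leaves V16A as the only pair to set against LNCaP, so that fit cannot decide. The calls became 126, of which 47 were lower and the rest higher, with DESeq2 size factors. They were 251 higher and 220 lower with the Wald test of DESeq2, 213 and 169 with no filter, and 2 to 239 higher and 1 to 596 lower with single pairs left out. For circRNAs 1 was higher with DESeq2 size factors, with at least 5 counts, with nuclear protein-coding scaling and at most with single pairs left out (0 to 1).

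DHT changes of genes (273 and 164) became 150 and 235 with library totals, 115 and 47 with the Wald test of DESeq2, 76 and 22 in the libraries with RNase R, 106 and 32 with no hours term, and 57 to 180 and 12 to 120 with single libraries left out and no hours term, where a lone library is assumed to vary like the others. CSNK1G3 stood at -0.0899 with library totals. In those fits HIST1H2AJ ran from -0.0091 (the 10 nM library at 4 h left out) to 1.39 (0 nM at 4 h left out). DHT changes of circRNAs (2 and 4) became 0 and 0 with the Wald test of DESeq2 and with no hours term. In all 8 LNCaP libraries with a term for each hours and RNase R combination, edgeR called 5 of 10811, and 2 of the 6 called circles lost their calls. In that fit both portions of 1 RNA count as separate libraries. The limit to circRNAs counted in all 4 libraries (0 and 0) leaves out all 6 called circles by construction, so it does not bear on them. They were 0 and 2 without RNase R, and 0 to 1 and 0 to 15 with single libraries left out and no hours term, where circles counted in the reduced arm alone were not tested. With an estimated correlation 0 gene lists passed for RNase R, 0 for DHT and 0 for the difference between lines, against 6, 9 and 5. For DHT this check cannot decide, since its fit leaves 1 residual degree of freedom.

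In 42D the epithelial median became 0.36 and that of circRNA host genes 0.51 with library totals, a scaling that raised random lists too (medians 0.92 and 0.90), and the lists stayed at percentiles 1.19 and 0.29. With 0.1 CPM in place of 1 CPM added, which also left fewer members in these lists, medians of androgen-repressed genes became -4.74 in 22Rv1, -2.29 in 42D, -6.36 in PC-3 and -3.31 in V16A, those of neuroendocrine genes 4.33 in 22Rv1, 1.51 in 42D and 2.82 in PC-3, that of basal epithelial genes 2.23 and of nuclear long noncoding RNAs -2.30 in PC-3, and that of androgen-induced genes -0.90 in 22Rv1. Mitochondrially encoded genes had medians of -0.23 in 42D, -0.14 in V16A and 0.32 in 22Rv1 with library totals, and of -0.72, -0.49 and 2.37 in the libraries with RNase R. In the latter, medians in 22Rv1 were -0.39 for ribosomal protein, -0.44 for epithelial and 2.45 for histone genes, those of proliferation genes 1.49 in 42D and 1.59 in V16A, and those of regulators of circRNAs 0.41 and 0.38 in these lines. With library totals, medians became 2.22 in 42D and 1.01 in V16A (androgen-induced), -0.75 in 42D (androgen-repressed), -0.44 (lipid synthesis) and -1.06 (epithelial) in PC-3, 1.75 in PC-3 and 1.12 in V16A (housekeeping), 0.83 in V16A (other cell types), and 0.23, 1.04, 1.10 and 0.81 in 22Rv1, 42D, PC-3 and V16A (regulators of circRNAs). In 42D 11 lists, in place of 7, lay outside the middle 95% of random lists in the libraries with RNase R. Correlations of circRNAs with host genes were 0.411 (22Rv1), 0.646 (PC-3) and 0.537 (V16A) with all circles summed; 0.472, 0.521 (42D), 0.668 and 0.549 at a mean of 20 counts; and 0.148, 0.263 (42D), 0.401 and 0.255 from libraries without RNase R. Libraries without RNase R held 6966 to 13322 circRNA counts.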

Other observations

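No test in this part was planned. Single replication-dependent histone genes were counted in some lines and nearly absent from others. The CPM values here use TMM factors over all 16 libraries, and those of the comparison of cell lines use factors over the 8 libraries without RNase R, so the same gene can have a different value there. HIST1H1D, a linker histone gene, had 189 CPM in PC-3 without RNase R and no count in 22Rv1, V16A and LNCaP. HIST1H3F (60.4 CPM) and HIST1H2BH (23.5 CPM) were likewise counted in PC-3 and had 1 count in 22Rv1 and none in V16A and LNCaP. In the opposite sense, PC-3 had 1 count of HIST1H1B, against 64.9 CPM in 22Rv1, 134 in 42D and 201 in V16A, and 2 counts of HIST1H3I, against 43.4 CPM in V16A. HIST1H4D (50.3 CPM) and HIST1H4L (8.25 CPM) were counted in 22Rv1, with at most 0.232 CPM of HIST1H4D in the other lines. In 42D, HIST1H3E had no count and HIST4H4 had 4, against 31.8 CPM of HIST4H4 in PC-3 and 12.4 in V16A. Each line had 1 library without RNase R, so these values have no replicate check, and copies of histone genes can share reads.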
